A study of Mus musculus with 4 samples.

How the data were processed

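Total liver RNA of male B6SJL hybrid mice was profiled on Affymetrix MG_U74Av2 arrays, 2 from wild-type and 2 from PEPCK-TAg transgenic mice. Per the labels, the animals were 58 to 60 days old and had eaten a diet of 10% protein and 70% carbohydrate for 4 weeks after weaning, and the RNA was extracted with RNA STAT-60 and labelled by the manufacturer's protocol. The PEPCK-TAg transgene places the SV40 large T and small t antigens under the promoter of the phosphoenolpyruvate carboxykinase gene, Pck1. Groups and replicate numbers were taken from the sample titles. The labels do not say that the arrays of a group came from separate animals and speak of duplicate measurements. The p-values of single probe sets therefore measure only the spread between these arrays, which may be technical in PEPCK-TAg. For wild type, gaps given under the other observations argue against the same RNA measured again.

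The deposited values are MAS5 signals on a linear scale, 1 per probe set and array, per the submitters' processing notes. The software version, the scaling target and any detection calls are not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets was 250.2 on each of the 4 arrays, so the deposited signal had been scaled to one target and was used without further normalization. The experiment files deposited for each array hold instrument records and no expression values. Per the file headers and fields, the 4 arrays shared chip type, chip lot, fluidics station, hybridization time and scan day, and each array had its own fluidics module and scan time, so no batch held more than 1 array short of all 4.

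Gene symbols came from the platform annotation supplied with the values. Of 12488 probe sets, 66 were controls and stayed out of every test. Of the other 12422, 10833 had 1 gene symbol, 396 had several and were given no name, and 1193 were unnamed here. Entrez identifiers matched the RefSeq gene table of the GRCm38.p6 assembly for 10817 of the named probe sets, with 0 symbols updated, giving 8251 genes. That table was used for names only, and no coordinates are given because no genome build belongs to these values.

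Signals were analysed as log2(signal + 13), the offset being 5% of the mean trimmed mean. Probe sets were kept when their mean log2 value reached the 40th percentile of the non-control probe sets, which left 7453 probe sets and 5650 genes, with a lowest kept mean near a signal of 48.1. A fold change on this scale understates the change of dim genes. PEPCK-TAg was compared with wild type, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual and 4.61 prior degrees of freedom. An exact permutation test of 2 arrays against 2 could not give a p below 0.333, so none was run. The number of arrays limits the precision of every value. A gene was represented by its probe set with the highest mean.

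A total of 32 gene lists (923 genes, of which 723 were on the array and 598 were measured after the filter) were written before the data were examined, as were the main tests, the alternatives and the rule for naming genes. Tests chosen after the result was seen are named under the other observations. Lists with at least 5 measured genes (31) were tested with camera of limma at a preset correlation of 0.01 between genes. The p-values of that preset test rest on the spread over genes, taken as nearly independent, and not on the spread between arrays. The lists were tested again with an estimated correlation. With 2 residual degrees of freedom that estimate is imprecise and its test has little power over 31 lists. Interferon response had an estimated correlation of -0.031, below the preset 0.01. Its unadjusted camera p was 6.80e-13 in the preset test and 0.0150 with the estimate. Not passing with the estimate therefore does not show that correlation between genes explains a call. Members past the threshold were also counted with p-values adjusted over the list alone. Named genes were, first, the 15 largest rises and the 15 largest falls among genes past the threshold with non-overlapping groups. In each list, up to 4 members of smallest p and the members past the threshold could be named. Always named were Pck1, Trp53, Rb1, Mdm2, Cdkn1a, Ccnd1, Afp, Alb, Mki67 and Pcna. Trp53 was not analysed here, because its probe sets carried only the symbol of a pseudogene. Probe sets whose suffix marks sequence that can be shared with other transcripts read Cyp7b1, H3c14, Apoa5, Atf3, Nop58, Pcx, Alas2, Ghr, Igfbp4, Igf1, Fas, Gstm3, Srxn1, Tubb6 and Mmp12. These values can hold signal of related genes. Some genes, such as Atf3, Btg2, Mt1, Mt2 and Cyp7b1, stand in more than 1 list.

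The procedure was tested on simulated arrays built from the means and spread of the real ones for PEPCK-TAg against wild type over 7453 probe sets. It recovered 70.1% of 67 probe sets changed by 1 on the log2 scale and 100% of those changed by 2 or 3, and 11 of 191 calls were false. On 31 simulated lists, camera called the 1 shifted list and 0 of the 30 others. Simulated genes varied independently of each other, so false calls caused by correlated genes could not appear. Among the real lists, that of male-biased genes had an estimated correlation of 0.68.

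Alternatives for the values were quantile normalization, median centring, cyclic loess, offsets of 1 and 50, no filter and a filter at the 60th percentile. Alternatives for the test were eBayes without the trend or with robust estimation, an adjusted threshold of 0.1, a fold rule, 1 probe set per gene, exclusion of shared-sequence probe sets, each array left out and the replicate number as a block. For the lists they were an estimated correlation, fry, ranks and the mean of a gene's probe sets. Where 1 array was left out, the lone array of its group was assumed to vary like the others.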

Results

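Gene expression was measured in total liver RNA of male mice, with 2 arrays from wild-type animals and 2 from PEPCK-TAg animals, which carry the SV40 large T and small t antigens under the Pck1 promoter. Both groups ate the same diet of 10% protein and 70% carbohydrate. The series asks how prolonged exposure to low levels of these viral oncoproteins alters gene expression in the liver, and the arrays allow 1 comparison, PEPCK-TAg against wild type. Each array gave 1 MAS5 signal for each of 12488 probe sets, with the same trimmed mean of 250.2. Signals of the 2 wild-type arrays correlated with r = 0.965 across probe sets, and those of the 2 PEPCK-TAg arrays with r = 0.966, against 0.896 to 0.914 between groups, where probe sets are not independent replicates. The ratio of the 3' to the 5' actin control signal was 4.87 and 4.06 on the wild-type arrays and 5.06 and 4.79 on the PEPCK-TAg arrays. That of Gapdh was 3.67 and 3.80 on the wild-type and 3.36 and 2.95 on the PEPCK-TAg arrays. The geometric mean signal of 9 spike-in probe sets was 833 and 1653 on wild-type replicates 1 and 2 and 666 and 604 on the PEPCK-TAg arrays.

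As lists, genes of cell division, interferon response and macrophages were higher in PEPCK-TAg liver, and genes of cholesterol, fatty acid and bile acid synthesis lower, by camera of limma with a preset correlation. None of these lists passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.349, and 0.386 for macrophages), and 8 of 24 macrophage and 6 of 16 fatty acid synthesis genes passed on their own. Mki67, a marker of dividing cells, had a signal of 7.25 ± 2.05 (SD, n = 2) in wild type and 551 ± 170 (SD, n = 2) in PEPCK-TAg, and the mitotic kinase gene Cdk1 rose from 12.1 ± 2.12 to 557.5 ± 55.1. Hsd3b5, a steroid dehydrogenase gene typical of male liver, fell from 4955 ± 496 to 355 ± 249, and Igfbp2, which encodes a binding protein for insulin-like growth factors, fell from 2920 ± 938 to 256 ± 112. Of 7453 probe sets tested, 477 were higher and 229 lower in PEPCK-TAg (limma, Benjamini-Hochberg adjusted p under 0.05), and the groups did not overlap in any of these 706, where 56.5% of all tested probe sets and 33.3% by chance have groups apart. With arrays centred on their medians, which shifted the median of all probe sets to -0.12, the split was 419 higher and 397 lower. The higher count was 294 without wild-type replicate 1, and the lower count was 94 without wild-type replicate 1, 140 without wild-type replicate 2, 145 without PEPCK-TAg replicate 1 and 147 without PEPCK-TAg replicate 2.

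**Figure D1:**
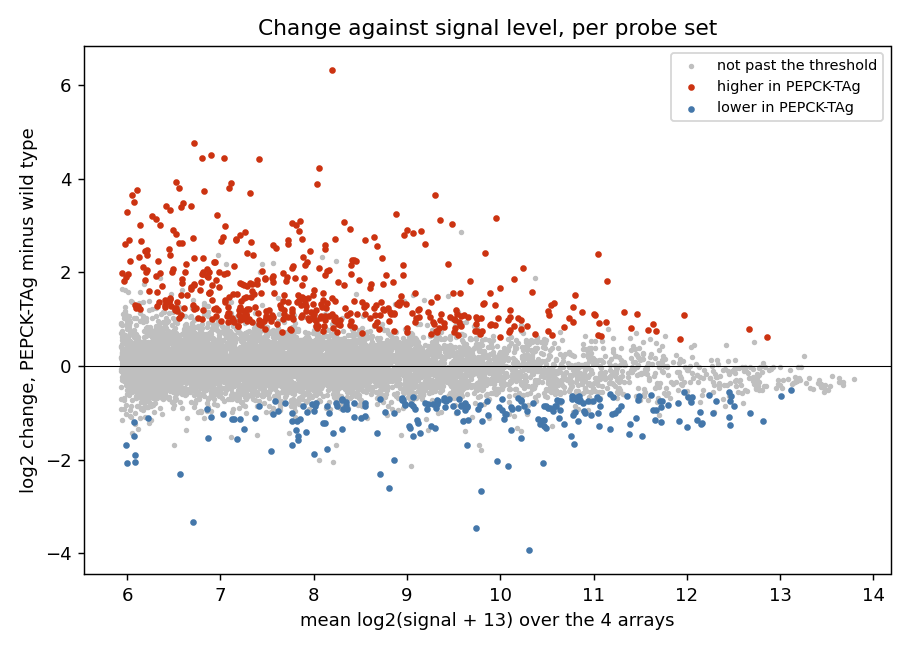
Each point is 1 of 7453 probe sets, with its mean log2(signal + 13) over the 4 arrays on the x axis and its log2 change, PEPCK-TAg minus wild type, on the y axis. Red points mark the 477 higher and blue points the 229 lower probe sets in PEPCK-TAg.

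The largest rise was that of D17H6S56E-5, by 6.33 ± 0.28 (SE) on the log2 scale, from a signal of 20.3 ± 8.77 to 2675 ± 799 (limma, Benjamini-Hochberg adjusted p = 0.000573). Mki67 (4.77), Cdk1 (4.51) and Ckap2 (4.44), all genes of dividing cells, followed, with Hao2 (4.44), Lcn2 (4.43), Cyp2b9 (4.23), Sult2a2 (3.94), Wfdc2 (3.91), Mcm5 (3.90), Mmp13 (3.80), Ccl2 (3.75), Stmn1 (3.67), Top2a (3.65) and Mt1 (3.41) completing the 15 largest rises in log2. Both PEPCK-TAg arrays lay above both wild-type arrays for each of them, although signals within a group could differ widely, as for Ccl2 with 5.50 and 38.7 in wild type and 238 and 674 in PEPCK-TAg. The second probe set of Mki67 did not share the rise, with a mean signal of 90.5 in wild type and 72.6 in PEPCK-TAg. The largest falls in log2 were those of Hsd3b5 (-3.94), Igfbp2 (-3.47), the elongase gene Elovl3 (-3.33), H3c14 (-2.61), Dnajc11 (-2.31), Msmo1 (-2.31), Cyp7b1 (-2.14), Hsd3b2 (-2.07), Cyp8b1 (-2.03), Etfbkmt (-2.01), Slc46a1 (-1.82), Ap2b1 (-1.69), Avpr1a (-1.68), Fdps (-1.67) and Tspan33 (-1.58). The calls of 4 of these falls were lost in at least 1 fit that left out an array. By limma with Benjamini-Hochberg adjustment, Elovl3 had an adjusted p of 0.0509 without wild-type replicate 1, and Msmo1 of 0.112 without wild-type replicate 2 and 0.0549 without PEPCK-TAg replicate 1. Hsd3b2 had 0.132 and 0.078 without wild-type replicates 1 and 2, and Ap2b1 had 0.104, 0.0819 and 0.0626 without wild-type replicates 1 and 2 and PEPCK-TAg replicate 2. The change of Hsd3b2 was -1.31 without PEPCK-TAg replicate 2.

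**Figure D2:**
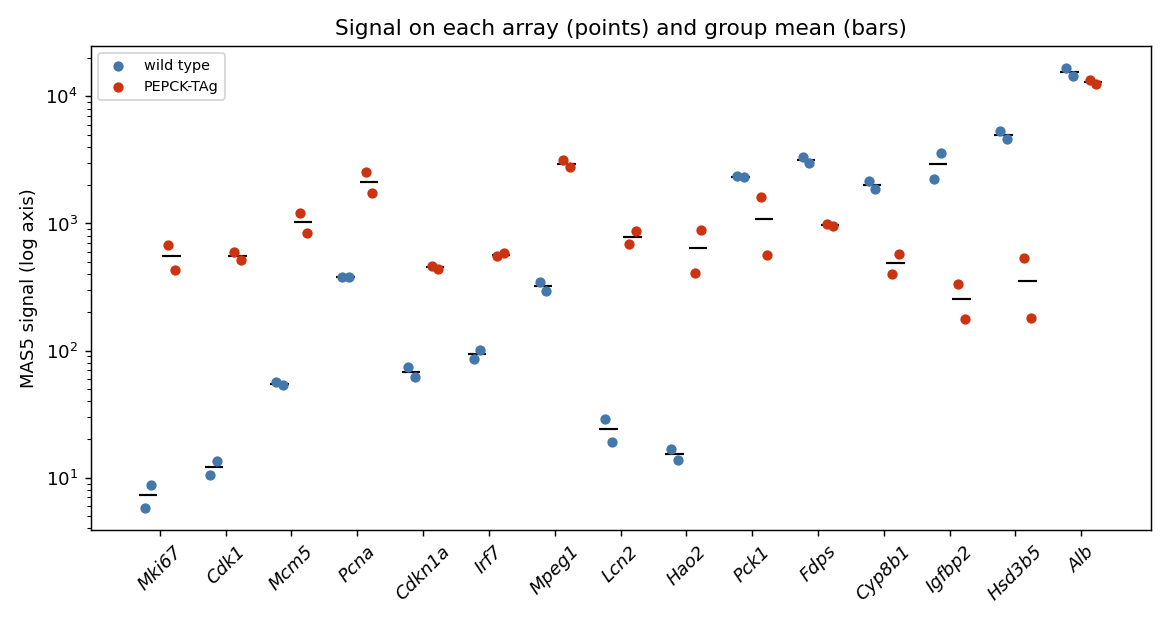
Points give the MAS5 signal of each array for 15 named genes on a log axis, blue for the 2 wild-type and red for the 2 PEPCK-TAg arrays, and bars give group means. Mki67 lies at 5.80 and 8.70 in wild type and at 672 and 431 in PEPCK-TAg, whereas the 2 groups lie close together for Alb.

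The lists of mitosis and DNA replication genes were higher by the preset test of limma camera, and neither passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.349 for each). Of 37 measured mitosis genes, 35 rose and 2 did not pass the threshold, with a median log2 change of 2.56, and 36 rose when adjusted over the list alone. Cyclin B2 (Ccnb2) rose from 210 ± 31.7 to 1908 ± 7.07 and the cytokinesis gene Prc1 from 64.2 ± 7.78 to 455 ± 85.1. Of 41 measured genes of E2F and DNA replication, 29 rose and 1, Mcm10, fell by 1.17 on the log2 scale. The list median was 1.57, and the counts were 37 and 1 when adjusted over the list alone. The replication clamp gene Pcna rose from 381 ± 0.99 to 2134 ± 542, and Mcm5, which encodes a subunit of the replicative helicase, from 55.1 ± 2.62 to 1018 ± 259. Rb1, whose product large T binds, measured 58.1 ± 9.26 and 67.2 ± 22.6, and Ccnd1 404 ± 231 and 200.4 ± 82.3, with limma Benjamini-Hochberg adjusted p of 0.806 and 0.237. By camera of limma with Benjamini-Hochberg adjustment, the mitosis list had an adjusted p of 3.92e-29 and the replication list of 6.24e-20, each with adjusted p = 0.349 with an estimated correlation. Without PEPCK-TAg replicate 1 the count of higher replication genes was 19. Mcm10 was not called without wild-type replicate 2 (adjusted p 0.101) or PEPCK-TAg replicate 2 (adjusted p 0.098).

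The lists of p53 targets and of genes of fetal liver and liver tumours were also higher by the preset test of limma camera, and neither passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.349 for each). Of 17 measured p53 targets, 3 rose, Cdkn1a (2.52 ± 0.18, log2 change ± SE), Btg2 (1.94 ± 0.22) and Apaf1 (1.28 ± 0.25), and 4 when adjusted over the list alone. Mdm2, which encodes the ubiquitin ligase of p53, measured 374 ± 60.5 in wild type and 512 ± 48.8 in PEPCK-TAg and did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.187). Of 15 measured oncofetal genes, 5 rose, and 10 when adjusted over the list alone. Glypican 3 (Gpc3) rose from 72.4 to 623, by 2.88 ± 0.24 in log2, and Anxa2 from 224 ± 41.3 to 1061 ± 282. The fetal serum protein gene Afp measured 43.7 ± 9.83 and 81.4 ± 8.63 (limma, Benjamini-Hochberg adjusted p = 0.148). Its other probe set, below the filter, did not share that direction, with 37.2 and 26.8 in wild type and a mean of 21.8 ± 15.8 in PEPCK-TAg. List medians were 0.47 for p53 targets and 1.12 for oncofetal genes. Camera of limma with Benjamini-Hochberg adjustment gave an adjusted p of 0.0117 and 8.85e-05, with an adjusted p = 0.349 with an estimated correlation for each. Apaf1 lost its call without any 1 of the 4 arrays, with limma Benjamini-Hochberg adjusted p of 0.0593 and 0.0539 without wild-type replicates 1 and 2 and 0.0719 and 0.144 without PEPCK-TAg replicates 1 and 2. The p53 list lost its call with the filter at the 60th percentile (adjusted p 0.121).

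The lists of interferon and macrophage genes were higher by the preset test of limma camera, and neither passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.349 and 0.386). Of 27 measured interferon response genes, 17 rose and 10 did not pass, with a median log2 change of 1.30, and 21 rose when adjusted over the list alone. The transcription factor gene Irf7 rose from 93.9 ± 10.7 to 569.5 ± 19.8 and Gbp3 from 179 ± 39.5 to 1314 ± 60.8. Of 24 measured macrophage and neutrophil markers, 8 rose, with a median of 1.11, and 15 rose when adjusted over the list alone. Mpeg1, a macrophage gene, rose from 322 ± 38.6 to 2960 ± 260.1 and Cd5l from 599 ± 308 to 1827 ± 331. By camera of limma with Benjamini-Hochberg adjustment the interferon list had an adjusted p of 7.03e-12 and an adjusted p = 0.349 with an estimated correlation, and the macrophage list 3.23e-07 and an adjusted p = 0.386 with an estimated correlation. The macrophage count was 5 without wild-type replicate 1, where the list median was 0.72, and 3 without PEPCK-TAg replicate 2.

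Markers of other cell types differed from list to list. Of 16 measured endothelial markers, 0 passed the limma threshold, or passed it when adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05, with a median of -0.45. Of 21 stellate cell and matrix genes, 2 rose, and 3 when adjusted over the list alone, with a median of 0.26. The collagenase gene Mmp13 rose by 3.80 ± 0.28 (log2 change ± SE) and Col3a1 by 1.44 ± 0.29, with a change of 0.50 in the other Col3a1 probe set (limma, Benjamini-Hochberg adjusted p = 0.392). Camera of limma with Benjamini-Hochberg adjustment gave an adjusted p of 0.0212 for lower endothelial markers and 0.0377 for higher stellate genes, and adjusted p = 0.585 and adjusted p = 0.565 with an estimated correlation. The endothelial call was lost without wild-type replicate 2 (median -0.15), without PEPCK-TAg replicate 1 (median -0.06) and with the filter at the 60th percentile (adjusted p 0.11). The stellate call was lost without wild-type replicate 1 (adjusted p 0.056), without wild-type replicate 2 (adjusted p 0.0886) and without PEPCK-TAg replicate 2 (median 0.04), each leaving 1 gene called, and with quantile normalization, cyclic loess or the filter at the 60th percentile (adjusted p 0.131). Its median was 0.49 without PEPCK-TAg replicate 1, and Col3a1 itself was not called without wild-type replicate 1 (adjusted p 0.096), wild-type replicate 2 (adjusted p 0.0679) or PEPCK-TAg replicate 2 (adjusted p 0.0594).

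The 8 measured genes of the bile duct list had a median of 0.60, which was 0.40 without PEPCK-TAg replicate 2 and 0.35 with quantile normalization. Krt8 and Krt18 of that list already measured 1134.5 and 1185.5 in wild type, so their rise alone does not show more bile duct cells. Of the 8 genes 3 rose, Krt8 (1.26), Krt18 (1.03) and Anxa4 (0.75), the same count as when adjusted over the list alone. Without wild-type replicate 1 or PEPCK-TAg replicate 2 only Krt8 of these was called. Of 9 red blood cell genes carbonic anhydrase 2 (Car2) rose by 2.27, also when adjusted over the list alone, with a list median of 0.18 and a mean of 0.04 while the test pointed down. That median was 0.07 and -0.12 without wild-type replicates 1 and 2, -0.03 and 0.01 without PEPCK-TAg replicates 1 and 2, and -0.14 with the filter at the 60th percentile. Alas2 measured 250.2 and 1073 on the wild-type arrays and 91.0 and 157 on the PEPCK-TAg arrays. Its log2 change of -2.01 with all arrays did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.0968). The change was -3.03 without wild-type replicate 1 and smaller in size than -2.01 without wild-type replicate 2. Of 7 B and plasma cell, 6 pancreas and 7 adipose and muscle genes, 0 passed the limma threshold, or passed it when adjusted over the list alone. At an unadjusted p under 0.05 there were 2 B and plasma cell genes, 1 higher and 1 lower, 1 higher pancreas gene and 1 lower adipose and muscle gene. Their medians were 0.02, -0.14 and -0.01, and that of B and plasma cell genes was below 0 with quantile normalization (-0.11), median centring (-0.11) and cyclic loess (-0.05). The B and plasma cell median was 0.18 and -0.05 and the adipose and muscle median 0.17 and -0.20 without wild-type replicates 1 and 2, and the pancreas median was -0.04 without PEPCK-TAg replicate 1. None of these 5 lists passed camera of limma, with Benjamini-Hochberg adjusted p of 0.209, 0.946, 0.903, 0.652 and 0.286 in the order given. The 2 measured T and natural killer cell markers were too few to test.

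Stress and acute phase genes changed in part. Lcn2, which encodes an iron-carrier binding protein of the acute phase, rose by 4.43 ± 0.22 (log2 change ± SE), while its other probe set changed by 0.05 (limma, Benjamini-Hochberg adjusted p = 0.916). The metallothionein genes Mt1 and Mt2 rose by 3.41 ± 0.36 and 3.03 ± 0.30. With Saa3, Cd14 and Il1rn these were 6 rises among 24 measured acute phase genes, and 9 rises and 4 falls when adjusted over the list alone. The list median was 0.01 (-0.12 with median centring, 0.16 without wild-type replicate 1, -0.03 without wild-type replicate 2, and -0.08 and 0.09 without PEPCK-TAg replicates 1 and 2). The list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.212), though it did with quantile normalization (adjusted p 0.0214), cyclic loess (adjusted p 0.0376) and without wild-type replicate 1 (adjusted p 0.0466). Of 26 heat shock and immediate early genes, 7 rose, and 10 rose and 1 fell when adjusted over the list alone, with a median of 0.42. Fos rose from 34.8 ± 13.2 to 399 ± 242, and Jun (2.07 ± 0.34), Atf3 (2.71 ± 0.23) and Klf6 (1.99 ± 0.17) rose as well. The list had a limma camera Benjamini-Hochberg adjusted p of 0.00505, and adjusted p = 0.468 with an estimated correlation. With the filter at the 60th percentile its median was 0.24 and its call was lost (adjusted p 0.0711). Of 29 genes of ribosome biogenesis and MYC, 6 rose, among them the nucleolar genes Nop58 and Nop56, and 1, Mxd4, fell, with 9 rises and 3 falls when adjusted over the list alone. The median was 0.21, with a limma camera Benjamini-Hochberg adjusted p of 0.0165, and adjusted p = 0.349 with an estimated correlation. Il1rn was not called without wild-type replicate 1 (adjusted p 0.0509), wild-type replicate 2 (adjusted p 0.0614) or PEPCK-TAg replicate 2 (adjusted p 0.0526). In the ribosome and MYC list 3 genes were higher without wild-type replicate 2 or PEPCK-TAg replicate 1, 0 were lower without wild-type replicate 1, wild-type replicate 2 or PEPCK-TAg replicate 1, and the median was 0.33 without PEPCK-TAg replicate 2.

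The lists of cholesterol, fatty acid and bile acid synthesis were lower by the preset test of limma camera, and none passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.349 for each). Of 15 measured cholesterol synthesis genes, 8 fell, with a median log2 change of -1.14, and 11 fell when adjusted over the list alone. Farnesyl diphosphate synthase (Fdps) fell from 3144 ± 233 to 980 ± 24.5 and lanosterol synthase (Lss) from 413 ± 24.3 to 169.8 ± 8.70. Of 16 fatty acid synthesis genes, 6 fell, with a median of -0.75, and 11 fell when adjusted over the list alone. The citrate carrier gene Slc25a1 fell from 2202 ± 268 to 905 ± 195 and the elongase gene Elovl5 from 9329 ± 825 to 4602 ± 176. Of 15 genes of bile acid synthesis and transport, 8 fell, with a median of -0.78 and the same count when adjusted over the list alone. The sterol hydroxylase gene Cyp8b1 fell from 2008 ± 207 to 487 ± 127 and Slc27a5, whose product activates bile acids, from 3339 ± 209 to 1630 ± 77.7. By camera of limma with Benjamini-Hochberg adjustment the adjusted p was 5.57e-09 for cholesterol, 6.50e-05 for fatty acid and 4.77e-05 for bile acid genes, and each had an adjusted p = 0.349 with an estimated correlation. The cholesterol count was 3 without wild-type replicate 2 and 5 without PEPCK-TAg replicate 1, and the fatty acid count was 2 without wild-type replicate 1 and 3 without PEPCK-TAg replicate 2. The bile acid count was 5 without wild-type replicate 1 or PEPCK-TAg replicate 1 and 4 without PEPCK-TAg replicate 2.

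Few genes of glucose metabolism, amino acid breakdown and fatty acid oxidation passed the threshold. Pck1, whose promoter drives the transgene, measured 2340 ± 45.3 in wild type and 1085 ± 735 in PEPCK-TAg, with 1605 and 566 on the 2 PEPCK-TAg arrays. With all arrays its log2 change was -1.28 and did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.121). The change was -2.02 without PEPCK-TAg replicate 1 and smaller in size than -1.28 without PEPCK-TAg replicate 2. In 17 genes of gluconeogenesis and glycolysis, 3 fell, the glucose-phosphate transporter gene Slc37a4 (-1.36 ± 0.20, log2 change ± SE), pyruvate carboxylase (Pcx, -1.28 ± 0.21) and pyruvate kinase (Pklr, -1.16 ± 0.22). The other probe sets of Pcx (-0.35) and Pklr (-0.78) did not pass (limma, Benjamini-Hochberg adjusted p = 0.562 and 0.0697). The count was the same when adjusted over the list alone, and the list median was -0.28. Of 27 genes of the urea cycle and amino acid breakdown, Agxt (-1.28 ± 0.24) and Gnmt (-0.76 ± 0.16) fell, and 5 when adjusted over the list alone, with a median of -0.31. Of 25 genes of fatty acid oxidation and PPARA, 0 passed the limma threshold, or passed it when adjusted over the list alone, and 1 was higher and 6 lower at an unadjusted p under 0.05, with a median of -0.25. By camera of limma with Benjamini-Hochberg adjustment the adjusted p was 0.000423, 8.85e-05 and 0.0117 for these 3 lists, with adjusted p = 0.349, adjusted p = 0.468 and adjusted p = 0.623 with an estimated correlation. The median of the fatty acid oxidation list was -0.56 without wild-type replicate 1 and 0.05 without wild-type replicate 2, -0.11 without PEPCK-TAg replicate 1 (adjusted p 0.101) and -0.43 without PEPCK-TAg replicate 2, and its call was lost with quantile normalization (-0.09) and cyclic loess (-0.10). Calls were lost for Pcx without wild-type replicate 2 (adjusted p 0.0541), for Slc37a4 (adjusted p 0.0509), Pklr (adjusted p 0.0699), Agxt (adjusted p 0.0537) and Gnmt (adjusted p 0.106) without wild-type replicate 1, for Pklr (adjusted p 0.0562) and Gnmt (adjusted p 0.0594) without PEPCK-TAg replicate 1, and for Gnmt without PEPCK-TAg replicate 2 (adjusted p 0.132). The urea cycle median was -0.53, with 4 genes lower, without wild-type replicate 2, 1 gene was lower without wild-type replicate 1 or PEPCK-TAg replicate 2, and its call was lost with quantile normalization (adjusted p 0.0627).

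Although all animals were male per the labels, the list of male-biased liver genes was lower and that of female-biased genes higher by the preset test of limma camera, and neither passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.468 and 0.349). Of 13 measured male-biased genes, 5 fell, Hsd3b5, Elovl3, Cyp7b1, Lifr and Cyp4a12b, with a list median of -0.75, and 9 fell and 1 rose when adjusted over the list alone. Cyp4a12b fell from 2722 ± 178 to 1342 ± 93.8. Of 8 measured female-biased genes, 4 rose, Hao2, Cyp2b9, Cyp2b13 and lipoprotein lipase (Lpl), with a median of 1.49 and 4 rises and 1 fall when adjusted over the list alone. Without a filter the median was 0.13 over 13 genes (limma camera, Benjamini-Hochberg adjusted p = 0.0210). Cyp2b13 rose from 15.9 ± 3.54 to 242 ± 148 and Lpl from 192 ± 58.5 to 1431 ± 139. In the list of growth hormone and IGF genes (23 measured), 4 fell, Igfbp2, Ghr, Igfbp4 and Igf1, as many as when adjusted over the list alone, with a median of -0.22. The falls of Igfbp4 and Igf1 each rest on a probe set with shared sequence, and their other probe sets changed by -0.10 and -0.38 (limma, Benjamini-Hochberg adjusted p = 0.824 and 0.275). By camera of limma with Benjamini-Hochberg adjustment, the adjusted p was 3.00e-05 for the male-biased, 0.0197 for the female-biased and 0.0177 for the growth hormone list, with adjusted p = 0.468, adjusted p = 0.349 and adjusted p = 0.559 with an estimated correlation. Without wild-type replicate 1 the male-biased median was -0.34 with 3 genes lower, and Elovl3 (adjusted p 0.0509) and Lifr (adjusted p 0.128) were not called, the latter also without PEPCK-TAg replicate 2 (adjusted p 0.103). The female-biased call was lost without wild-type replicate 1 (adjusted p 0.333) and with the filter at the 60th percentile (median 0.13), and its median was 2.65 without wild-type replicate 2. The growth hormone call was lost without wild-type replicate 2 (adjusted p 0.0745) and PEPCK-TAg replicate 2 (median -0.04), and the median was -0.38 without PEPCK-TAg replicate 1. Only Igfbp2 of that list was called without wild-type replicate 1 or PEPCK-TAg replicate 2, and Igf1 was not called without wild-type replicate 2 (adjusted p 0.112) or PEPCK-TAg replicate 1 (adjusted p 0.117) either.

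The lists of secreted plasma protein and drug metabolism genes were lower by the preset test of limma camera, and neither passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.386 for each). Of 40 measured plasma protein genes, 7 fell, with a median of -0.36, and 14 fell when adjusted over the list alone. Apoa5, which encodes a plasma apolipoprotein, fell from 6999.5 to 2959 ± 48.4, and albumin (Alb) measured 15576 ± 1621 and 12893 ± 632 without passing the threshold (limma, Benjamini-Hochberg adjusted p = 0.237). Of 31 drug metabolism genes, 3 fell, including Cyp1a2 from 5073 ± 1707 to 1747 ± 193, and Cyp2b10 rose from 69.4 ± 8.98 to 204 ± 54.5. The median was -0.38, with 4 falls and 1 rise when adjusted over the list alone. Camera of limma with Benjamini-Hochberg adjustment gave an adjusted p of 1.45e-09 for plasma proteins and 0.00460 for drug metabolism, and adjusted p = 0.386 with an estimated correlation for each. With quantile normalization the plasma protein median was -0.14 and its call was lost (adjusted p 0.0744), and with cyclic loess it was -0.13 (adjusted p 0.0162). The drug metabolism call was lost with quantile normalization (adjusted p 0.415), with cyclic loess (adjusted p 0.2) and without wild-type replicate 2 (adjusted p 0.0678). The plasma protein count was 1 without wild-type replicate 1, 3 without wild-type replicate 2, 3 without PEPCK-TAg replicate 1 and 2 without PEPCK-TAg replicate 2. Without wild-type replicate 1, 1 drug metabolism gene was lower, and Cyp2b10 was not called there (adjusted p 0.0652) or without PEPCK-TAg replicate 2 (adjusted p 0.0838).

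The remaining lists did not pass. Of 25 genes of NRF2 and glutathione, 4 rose (Mt1, Mt2, Gsta2 and Gstm3) and 2 were lower (Gsta3 and Srxn1), with a median of 0.18 and counts of 7 and 4 when adjusted over the list alone. The probe sets of Srxn1 disagreed, -0.72 in the one used, which can share sequence, and 1.89 in the other (limma, Benjamini-Hochberg adjusted p = 0.0478 and 0.035). Of 16 circadian genes, Wee1 and Nampt rose and Nr1d1, a repressor of the clock, fell, with the same counts when adjusted over the list alone. The median was 0.18, but 0.06 and 0.03 without wild-type replicates 1 and 2 and -0.16 with the filter at the 60th percentile. Among 21 genes of endoplasmic reticulum stress Atf3 rose, also when adjusted over the list alone, with a median of -0.15 and a mean of 0.03. That median was -0.05 without wild-type replicate 1, -0.22 without PEPCK-TAg replicate 1 and -0.08 without PEPCK-TAg replicate 2. Among 10 subunits and regulators of PP2A, the phosphatase that small t binds, 0 passed the limma threshold, and 1 was higher and 2 lower at an unadjusted p under 0.05, with a median of -0.03. That median was 0.14 and -0.12 without wild-type replicates 1 and 2 and 0.02 and -0.05 without PEPCK-TAg replicates 1 and 2. The higher PP2A gene, Set, passed when adjusted over the list alone. Limma camera with Benjamini-Hochberg adjustment gave adjusted p of 0.499, 0.821, 0.219 and 0.825 for these 4 lists. The NRF2 median was -0.09 and 0.35 without wild-type replicates 1 and 2, and 0.42 and -0.01 without PEPCK-TAg replicates 1 and 2. That list passed without PEPCK-TAg replicate 1 (adjusted p 0.0304), with 2 genes higher without wild-type replicate 1 or PEPCK-TAg replicate 2 and 0 lower without wild-type replicate 1, wild-type replicate 2 or PEPCK-TAg replicate 1. In the circadian list, Nampt was not called without wild-type replicate 1 (adjusted p 0.0655), PEPCK-TAg replicate 1 (adjusted p 0.0571) or PEPCK-TAg replicate 2 (adjusted p 0.0546), Wee1 not without PEPCK-TAg replicate 2 (adjusted p 0.0574), and Nr1d1 not without wild-type replicate 1 (adjusted p 0.0667), wild-type replicate 2 (adjusted p 0.111) or PEPCK-TAg replicate 1 (adjusted p 0.106). In the endoplasmic reticulum stress list 2 genes were higher without wild-type replicate 1 or PEPCK-TAg replicate 2.

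In all, 21 of 31 lists tested with camera of limma passed, 10 of them higher and 11 lower in PEPCK-TAg. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05. Lists whose estimated correlation lay below the preset one, such as interferon response (-0.031), did not pass either. The loss of calls therefore does not show an effect of correlation between genes.

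**Figure D3:**
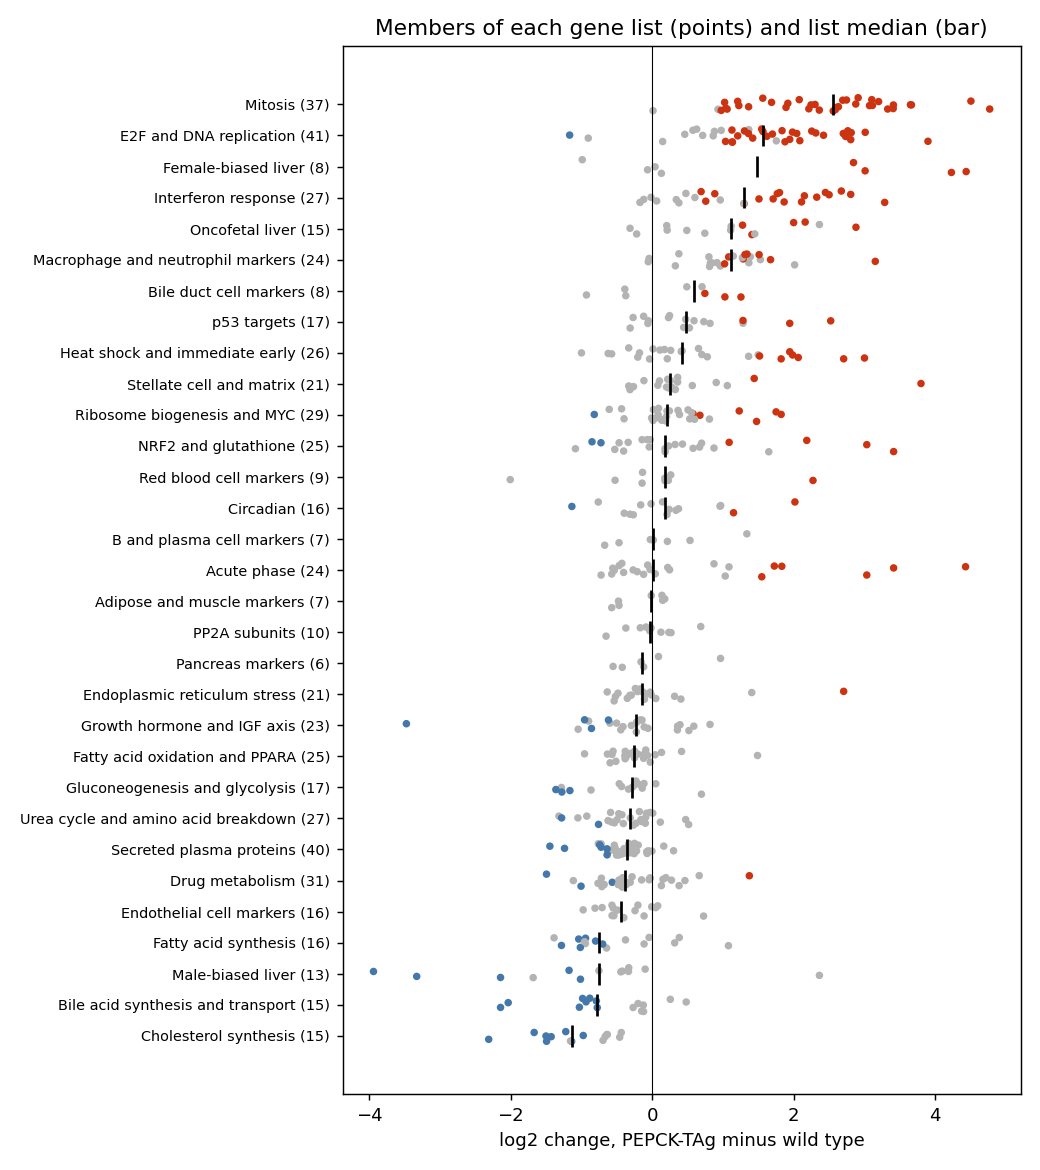
Each point is a gene of the list named on the y axis (number of measured genes in parentheses), placed by its log2 change, PEPCK-TAg minus wild type, with red for genes called higher, blue for genes called lower and grey for the rest, and bars for list medians. Medians run from -1.14 for cholesterol synthesis to 2.56 for mitosis.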

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

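Control probe sets for mouse genes, which no comparison used, were searched for higher signals in PEPCK-TAg. The one for Fas, a gene of the p53 target list, had signals of 127 and 146 on the wild-type arrays and 233 and 265 on the PEPCK-TAg arrays, a log2 change of 0.81. The gene's own probe set in the tested data measured 65.7 in wild type and 169 in PEPCK-TAg, a log2 change of 1.28 ± 0.33 (SE), with a limma Benjamini-Hochberg adjusted p of 0.062 with all arrays and 0.0173 without wild-type replicate 2. Lower signals were not searched for, but pyruvate carboxylase controls also lay apart, with 2322 and 2962 in wild type and 1322 and 1734 in PEPCK-TAg for the 3' probe set (log2 change -0.79) and 241 and 233 against 120.5 and 138 for a middle one (-0.81), the direction reported for Pcx. No biological or technical explanation was tested.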

How the results depend on the processing

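The counts of 477 higher and 229 lower probe sets moved by more than 1.5 times in some settings. The lower count was 397 with median centring, 105 without a filter, 117 without the variance trend, and counts were 741 and 448 at an adjusted threshold of 0.1 and 250 and 44 under the fold rule. Leaving out 1 array gave 294 to 401 higher and 94 to 147 lower probe sets. In the settings that keep all arrays, higher and lower counts not printed elsewhere in this paragraph lay between 337 and 485 and between 186 and 238, within 1.5 times. The threshold and the fold rule change the counts by their construction, as does testing 12422 probe sets without a filter. Leaving out 1 array lowers the residual degrees of freedom, which by itself can lose calls. The cause was not tested for the others. Of the 31 lists, 0 passed with an estimated correlation (smallest adjusted p 0.349) and 8 with fry, 7 of which also passed in the preset test, against 16 to 21 in the other settings. The median of fatty acid oxidation and PPARA genes ran from -0.56 to 0.0470 when 1 array was left out, turning direction without wild-type replicate 2. The turn follows from a gap between the wild-type arrays, where 3 of 25 genes were higher on replicate 1 (median gap -0.49). Why those arrays differed was not tested. Of 369 list values, 322 kept direction and side of the threshold, 23 lost the call, 4 gained it, 19 changed sign without a call and 1 reversed. For the 238 genes named by the rule, 2819 of 3252 values kept direction and side, 389 lost and 36 gained a call, 8 uncalled values changed sign and 0 called values reversed. Titles give the same numbers to both groups, but deviations of same-numbered arrays correlated at 0.181 over only 2 pairs, which does not pair the samples, and with the replicate number as a block counts were 696 and 444. The planned batch block was not run, since the arrays share every recorded batch or differ each from the others. Without detection calls, signals as low as that of Mki67 in wild type (7.25) cannot be set against background, which limits their folds.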

Other observations

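The comparison of macrophage with endothelial markers and the tests of a general loss of hepatocyte transcripts (also without a filter) and of gene families were chosen after the result was seen. Genes outside the lists that were chosen after their values were seen, by smallest p among genes of no list, moved strongly. Tubb6, a tubulin gene whose probe set can share sequence with other transcripts, rose by 2.61 ± 0.18 (log2 change ± SE), and the cytoplasmic actin gene Actg1 rose by 1.81 ± 0.16. The chemokine gene Cxcl1 rose by 2.69 ± 0.19, the macrophage elastase gene Mmp12 by 3.23 ± 0.23 and the adhesion gene Vcam1 by 2.71 ± 0.21. Golm1, which encodes a Golgi membrane protein, rose by 2.09 ± 0.19, and Slc25a4, which encodes a mitochondrial ADP/ATP carrier, by 2.49 ± 0.22. The hepatocyte genes Hsd11b1, Rgn and Car5a fell by 1.16, 1.01 and 1.33. All had limma Benjamini-Hochberg adjusted p under 0.05, the largest being 0.00824 for Car5a. Among 39 gene families defined by symbol, 1 passed camera, the Trim genes, of which 2 of 10 rose (limma camera, Benjamini-Hochberg adjusted p = 0.0266, and adjusted p = 0.888 with an estimated correlation).

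The 2 arrays of a group differed from each other in some lists. Of 25 fatty acid oxidation genes 3 were higher on wild-type replicate 1 than on wild-type replicate 2. Cyp4a14, chosen after its values were seen, measured 39.2 and 2543 there and 254 and 444 on the PEPCK-TAg arrays. Cyp4a10 and Acot1, chosen likewise, measured 95.4 and 2432 and 141 and 614 on the wild-type arrays. With a median gap of -0.49 over the list, these values argue against the same RNA measured again on the wild-type arrays. For the PEPCK-TAg arrays that question stays open. Of 37 mitosis genes 34 were higher on PEPCK-TAg replicate 1 than on PEPCK-TAg replicate 2, with a median gap of 0.42. Macrophage and neutrophil markers were lower on replicate 1 than on replicate 2 in both groups, with median gaps of -0.70 in wild type (6 of 24 higher on replicate 1) and -0.50 in PEPCK-TAg (4 of 24).

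Macrophage and interferon genes were higher in PEPCK-TAg as lists by the preset test, with 8 of 24 and 17 of 27 genes past the threshold, and not with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.386 and 0.349). A lower share of hepatocytes would raise other cell types alike, but the macrophage median exceeded the endothelial median by 1.56 (permutation test over genes, p = 1e-05, the smallest its 100000 resamples can give). That p treats genes as independent, although estimated correlations were 0.32 in the macrophage and 0.43 in the endothelial list. It does not measure the spread between arrays. The difference was 1.198 to 1.498 when any array was left out and 1.33 without a filter. The endothelial list was chosen after the result was seen and had the lowest median of the cell type lists tested. The permutation p takes no account of that choice. Medians of the other cell type lists tested ran from -0.14 for pancreas to 0.60 for bile duct, below the macrophage median of 1.11. Array scaling alone would shift every gene of an array alike, and the median log2 change of all probe sets was 0.01. That argues against scaling as the whole cause for these lists relative to the other genes. Centring, which removes such a shift, left medians of 0.99 for macrophage and 1.18 for interferon genes. By its construction it could not change the lists relative to the other genes. Quantile normalization, which also acts by signal level, left 1.10 and 1.36. The spike-in signals were not used to test scaling. An increase of macrophages or of their activity, or an interferon response of hepatocytes, may each account for the rise, and these data do not separate them.

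Secreted plasma protein genes were lower as a list by the preset test, with 7 of 40 past the threshold, and not with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.386). Dilution of hepatocyte RNA as the whole cause would lower them by one amount. The SD of the changes of 40 genes was 2.01 times the standard error expected from the arrays (0.33 against 0.16, chi-square p = 4.16e-16). That error comes from few arrays, of which those of PEPCK-TAg may be technical duplicates. The chi-square test also treats the genes as independent, although their estimated correlation was 0.26. The test therefore cannot decide on dilution. A trend of change with signal level cannot be told apart from the pattern, since the list median of -0.36 lay at the 2.13th percentile of 10000 random lists matched on signal, whose median was -0.22, and quantile normalization moved it to -0.14 and ended the call, and cyclic loess to -0.13. Part of the fall may be technical, and whether the transgene acts directly on these genes was not tested.

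Male-biased genes were lower (5 of 13 past the threshold) and female-biased genes higher (4 of 8) as lists by the preset test, and not with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.468 and 0.349), in animals labelled male. A general loss of hepatocyte transcripts cannot be told apart, since the female-biased median was 0.13 over all 13 genes on the array, with a standard error of the mean of 0.50, and the 1.49 over 8 filtered genes is raised by a filter that a rise from a low signal helps a gene to pass. Female RNA on the PEPCK-TAg arrays finds no support in the sex-linked genes but cannot be told apart: Xist (13.5 and 11.7 in wild type, 11.4 and 27.0 in PEPCK-TAg) changed by 0.29, with a 95% limma interval reaching 1.01, and no array of a female shows that its probe set detects it. Of the Y-linked genes, Eif2s3y measured 360.0 and 319 in wild type and 376 and 359.8 in PEPCK-TAg (0.11, interval -0.25 to 0.47) on a probe set that can share sequence, Uty changed by 0.36 (interval from -0.41) at signals of 44.6 and 48.1 in wild type, near the lowest kept, and Kdm5d by -0.28 at a mean signal of 8.65 in wild type. A change in growth hormone signalling is a further candidate explanation that was not tested.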
